A study of Homo sapiens with 21 samples.

How the data were processed

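The series holds 21 samples of 4 human melanoma cell lines (501mel, SKMEL-5, SKMEL-147 and A375), of which 15 come with a list of enriched regions and a list of summits. These 15 libraries cover ATAC-seq, which maps open chromatin, in 4 libraries, histone H3 K27ac, a mark of active promoters and enhancers, in 8 libraries, the insulator protein CTCF in 2 libraries, and HA-tagged HOXD13 in 1 library. The other 6 samples, 5 IgG libraries and the HA library of A375-GFP, were not analysed here. The growth protocol gives 72 h of culture with or without 1 µg/ml doxycycline, and the labels do not say which samples received it. They also do not say which libraries came from ChIP-seq and which from CUT&Tag. The hairpin names shH2 and shH3 carry no target in the labels. The series design states silencing or overexpression of HOXD13, and shNTC is read as the non-targeting control. The region names in the 501mel ATAC list contain siNTC, which its label does not mention, and whether these cells were transfected with a control siRNA is not stated.

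Per the submitters' processing notes, Trim Galore, Bowtie2, SAMtools, MACS2 and deepTools were used with the hg38 genome, without versions, settings or control libraries. Each deposited region list gives a score, which equals the whole part of 10 times the −log10 q for almost every region. It also gives the fold enrichment of the summit over the caller's background, a ratio computed by the authors. The deposited −log10 p and −log10 q come from the authors' caller as well, and the lowest −log10 q in every list was about 1.30. Folds and −log10 q are the authors' values, and they were used only to describe, rank and filter regions within a list. The lists hold no read counts, so the depth of each library is unknown, and the number of regions and their covered length stand in for it. Summit positions and −log10 q matched the region lists for every region. Regions on the autosomes and the X chromosome were kept. Of the 15 lists 5 also held regions on alternative copies of genome sequences, 374 (shH2) to 2747 (A375-GFP ATAC), so the libraries were not all aligned or filtered alike. In these 5, the shNTC, hairpin and A375-GFP ATAC lists, the MHC (28 to 34 Mb of chromosome 6) held 1.09 to 3.82% of the chromosome 6 regions. It held 1.93% of those of HOXD13-HA and 5.31 to 11.2% in the other 9 lists, so a missing region there is not evidence of missing signal. Other sequences with such copies were not examined.

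Regions were counted as shared when they overlapped by at least 1 bp. Shares are given with 95% Wilson intervals, which cover counting error only. For chance overlap, HOXD13-HA regions were placed 1000 times at random on their own chromosome, within 100-kb bins that hold a region of at least 1 library (100 placements for the annotation). Genes were the 19974 protein-coding genes of the RefSeq table for GRCh38. That table gives no strand and no exons, so distances run to the nearer of both gene ends instead of the transcription start, and exons and introns were not told apart, a deviation from the plan. Regions were called near a gene end (midpoint within 2 kb), in a gene or between genes. No genome sequence was at hand, so the planned motif counts were not run.

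The 18 gene lists (319 different genes, all matched, a few of them in more than one list) were the angiogenesis factors and receptors, class 3 semaphorins and plexins, adenosine pathway, antigen presentation, immune checkpoints and suppressive cytokines, chemokines and inflammatory cytokines, melanocytic genes, undifferentiated and invasive genes, HOX cluster genes, limb development genes, MAPK feedback genes, cohesin and CTCF partners, housekeeping genes, and genes of keratinocytes, T cells, fibroblasts, endothelium and hepatocytes. A gene counted as near a region when the region's midpoint lay within 50 kb of either end. Each count was placed among 10000 random lists of the same size, matched in 20 classes on the number of A375-GFP ATAC regions (HOXD13-HA), shNTC K27ac regions (lost) or hairpin K27ac regions (gained) in the same windows. The percentile describes these libraries and is not a p-value; with 18 lists, 0.9 would lie above the 95th percentile by chance.

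K27ac regions lost were those listed in both A375-shNTC replicates, merged, and in neither shH2 nor shH3; regions gained were listed in both hairpin libraries and in neither replicate. The same count was made for the other ways of pairing the 4 libraries. Loss at HOXD13-HA regions was compared with 1000 draws of unbound regions from the same of 10 classes of −log10 q and 10 classes of width, with the full range of the draws after a matched share and their middle 95% behind the interval after a difference. Open regions bound by HOXD13-HA were compared with unbound ones in the same way. These intervals cover the draws only, leave out the counting error of the bound share and treat regions as independent. They are thus narrower than an interval for the difference would be. For cell lines, the covered length within 50 kb of each gene was ranked among all protein-coding genes of the same library. A375-shNTC K27ac has 2 replicates and every other group has 1 library, and without read counts no test between groups was run. For the silencing comparison, each hairpin alone and each replicate left out serve as checks, and the other pairings are given beside them. Every other pairing puts an shNTC and a hairpin library on either side. Its count is therefore no background for the lost regions, and it cannot tell silencing from any other difference between shNTC and hairpin libraries.

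The named genes were fixed before the data were examined: HOXD13; from each list at most 4 genes in order of the highest HOXD13-HA fold; the genes nearest to the 10 strongest HOXD13-HA, lost and gained regions; at most 6 melanocytic and 6 undifferentiated genes by spread between lines; and VEGFA, SEMA3A and NT5E. Gene lists, groups, comparisons and most alternatives were fixed then too. Alternatives were a −log10 q of at least 10, an overlap of at least 50% of the shorter region, lists held to equal length by −log10 q, all sequences, summits alone, distances of 1 and 5 kb or 10 and 100 kb, the nearest gene end, unmatched lists, each hairpin alone, each shNTC replicate left out, regions within 1 kb joined, and other matching. The gene body with 50 kb, the matches on ATAC overlap and the lists without MHC genes were chosen after seeing the data.

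Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used. The overlap count was checked against bedtools 2.31.1, with equal results for 29176 of 29176 regions. On simulated data, 6% of 200 random lists reached the 95th percentile, and 87.5% did when 6 bound genes had been added. A simulated excess loss of 10.0 points at bound regions came back as 10.7 points after matching, and a simulated difference of 0 came back as −0.170 points. A simulated difference of −9.61 points came back as −9.91. The simulated loss depended on the same strength classes as the match, so this checks the code and not differences left within classes.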

Results

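The 15 region lists described 4 melanoma lines, with ATAC and K27ac in each line, CTCF in 501mel and SKMEL-5, and tagged HOXD13, a homeobox transcription factor of limb patterning, in A375. The ATAC lists held 56333 (SKMEL-5) to 163102 (SKMEL-147) regions. K27ac lists held 42115 regions in SKMEL-5, 55889 in 501mel, 58855 in SKMEL-147 and 139985 in A375-GFP. In the silencing series of A375, the shNTC replicates held 85977 and 80242 K27ac regions over 103 and 98.4 Mb. The hairpin libraries held fewer, 43634 over 36.8 Mb in shH2 and 51838 over 49.2 Mb in shH3. Their regions were also narrower, with median widths of 571 and 640 bp against 741 and 766 bp in shNTC. The CTCF lists held 39473 regions in 501mel and 51015 in SKMEL-5, and the HOXD13-HA list held 29176 regions over 10.7 Mb.

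**Figure D1:**
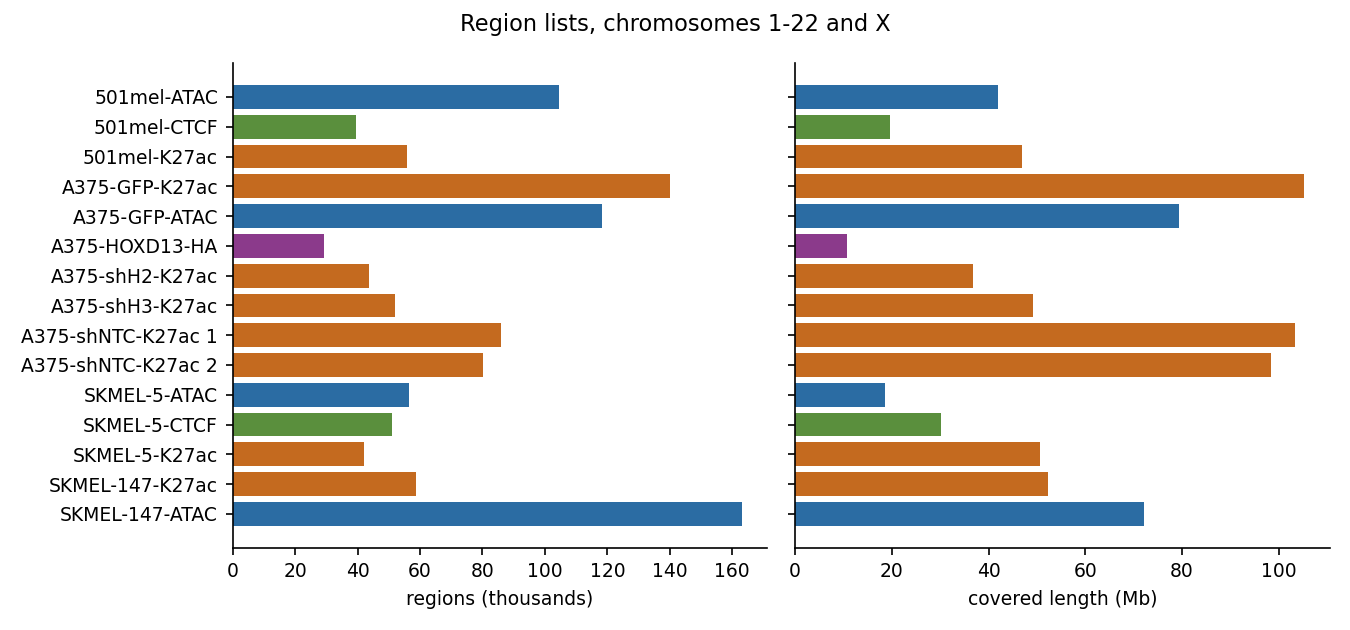
Number of regions on the autosomes and the X chromosome (left) and covered length in Mb (right) for each of the 15 libraries, 1 bar per library. The hairpin K27ac lists, with 43634 and 51838 regions, were shorter than both shNTC replicates, with 85977 and 80242.

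The HOXD13 gene itself (chromosome 2, 176087487 to 176095944, hg38) carried acetylation at or just beyond its upper end in every K27ac library of 501mel, SKMEL-5 and A375. The strongest such region ran from 176095697 to 176097399 in 501mel and from 176096032 to 176097996 in SKMEL-5. A375-GFP had one from 176096418 to 176097723. Both hairpin libraries and both shNTC replicates listed acetylated regions there as well, and since hairpins act on mRNA this does not by itself check the silencing. The authors' folds there were 2.13 and 2.03 in the shNTC replicates, 4.08 and 3.64 in shH2 and 7.28 in shH3. With depth unknown, these folds do not measure a change between libraries. Which end of the gene holds its promoter was not told apart, since the gene table gives no strand. SKMEL-147 had no K27ac region within 10 kb of HOXD13, although it listed open chromatin from 176097231 to 176098095, and all 4 lines were open at this place. CTCF lay over the same place, from 176096587 to 176098048 in 501mel and from 176096913 to 176098079 in SKMEL-5. No HOXD13-HA region overlapped the gene, and the nearest, from 176104175 to 176104697, lay 8230 bp beyond it.

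HOXD13-HA was frequent in the HOX clusters, the 4 chromosomal groups of homeobox genes that pattern the body axis. The clusters held 38 HOXD13-HA regions, 6.57 times the mean of 5.78 for random placements, whose range was 0 to 16. Of these, 10 lay in HOXA, 13 in HOXB, 12 in HOXC and 3 in HOXD. The strongest, with an authors' fold of 20.3, lay at 27139838 to 27140901 of chromosome 7 in HOXA. The placements were not matched on open or acetylated chromatin, so the excess is not shown to be particular to the clusters. In A375-GFP, K27ac covered 31.2% of HOXA, 32.8% of HOXB, 32.5% of HOXC and 4.91% of HOXD. A375-GFP ATAC regions covered 12.5, 10.7, 15.7 and 13.1% of these clusters. K27ac covered 8.52% of the HOXD cluster in SKMEL-5 and 0.631% in SKMEL-147.

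Tagged HOXD13 regions overlapped open and acetylated regions of A375-GFP more often than random placements did, and yet most of them lay outside both. No ATAC or K27ac library of the HOXD13-HA cells is among the samples. Whether these sites were open or acetylated in the cells that carried HOXD13-HA is therefore unknown. Of 29176 regions, 34.1% (33.5 to 34.6) overlapped A375-GFP ATAC regions, 7.77 times the random mean of 4.39%. A375-GFP K27ac overlapped 22.2% (21.7 to 22.7), 4.01 times the random mean of 5.54%. Both marks were present at 14.8%, ATAC alone at 19.2%, K27ac alone at 7.37%, and neither at 58.5%. The overlap with ATAC grew from 26.2% in the weakest of 10 strength classes of HOXD13-HA regions to 55.2% in the strongest. Seen from the other side, HOXD13-HA was present at 8.23% of A375-GFP ATAC regions, from 3.45% in the weakest of 10 strength classes to 12.7% in the ninth and 8.27% in the strongest. With all lists filtered to a −log10 q of at least 10, which left 6918 HOXD13-HA and 28370 K27ac regions, the shares were 41.0% in ATAC and 13.7% in K27ac. Against the full K27ac list the share rose with HOXD13-HA strength, to 31.8% in the strongest class. The HA library of A375-GFP, which would give the background of the HA antibody, was not analysed here.

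**Figure D2:**
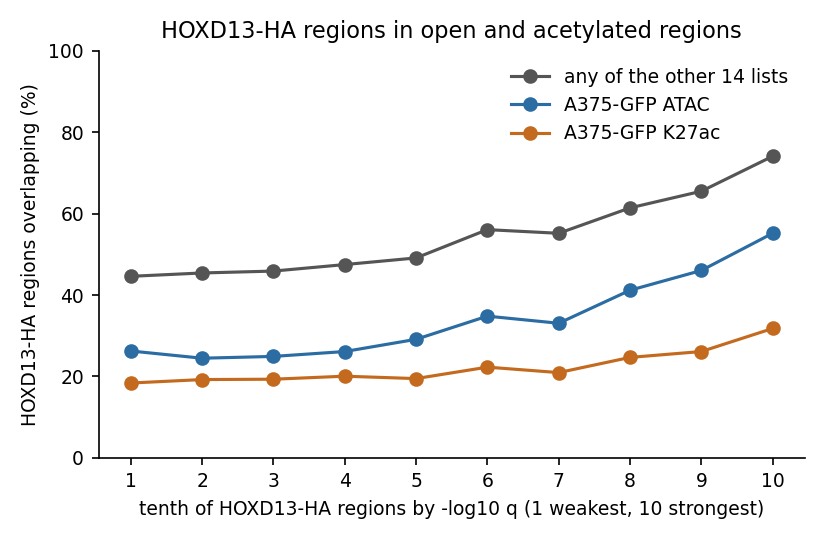
Share of HOXD13-HA regions (%) that overlapped A375-GFP ATAC regions, A375-GFP K27ac regions or any of the other 14 lists, in 10 classes of HOXD13-HA −log10 q from weakest to strongest. Overlap with ATAC rose from 26.2% to 55.2%, with K27ac from 18.4% to 31.8% and with any list from 44.6% to 74.1%.

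HOXD13-HA regions lay mainly within genes and between genes, away from gene ends. Near a gene end lay 5.51% of them, against 15.3% of A375-GFP ATAC regions, 16.3% of A375-GFP K27ac regions and 4.72% of random placements (4.45 to 5.12). Within genes lay 46.9% and between genes 47.6%. With the distance set to 1 kb the share near a gene end was 3.02%, and with 5 kb it was 10.5%. The region with the highest fold, 40.2, lay inside NTM, a neural cell adhesion gene, at 131997016 to 131998924 of chromosome 11, outside A375-GFP open and acetylated chromatin. The next 9 were nearest to SLC10A2, PLCH2, VPS13B, MUC12, ETS2, NPRL3, DYSF, PKDCC and TMED7, with folds from 31.2 to 21.1. Of the 10, 3 lay in A375-GFP open chromatin, those nearest to SLC10A2, an intestinal bile acid transporter, NPRL3 and PKDCC. The region assigned to SLC10A2 lay 364011 bp from it, that of DYSF 147308 bp and that of ETS2 125921 bp.

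The gene lists addressed whether HOXD13-HA gathers near genes of angiogenesis and immune evasion, which the series title names. A fold beside a gene name is that of its strongest HOXD13-HA region within 50 kb, in many cases outside the gene. Those of ADORA1, CXCL1, WNT5A and CTCF lay 33842, 46896, 46993 and 39558 bp from the gene. All 39 HOX genes had a HOXD13-HA region within 50 kb, against 25.4 for matched random lists (100th percentile). These genes form 4 loci and share 43 distinct regions, so they are not 39 separate observations. Adenosine pathway genes had one in 13 of 15 cases against 9.69 (96.4th percentile), led by the receptors ADORA1, ADORA2A and ADORA3 with folds of 8.31, 6.74 and 6.44 and by the kinase ADK with 5.66. Chemokine and cytokine genes had one in 14 of 18 cases against 10.3 (96.7th), led by the neutrophil attractants CXCL1 (8.07) and CXCL8 (5.93), then CCL20 (5.76) and CXCL12 (5.39). The 18 genes form 14 loci, 11 of them with a region, and CXCL9, CXCL10 and CXCL11, named after their values were seen, count through 1 shared region of fold 2.37. These 3 of 18 lists lay above the 95th percentile, where 0.9 would lie by chance. With regions assigned to the nearest gene end, the HOX list alone stayed above it, while the adenosine list came to the 70.8th percentile and the chemokine list to the 89.0th. With 10 kb these came to 89.5 and 46.8, with 100 kb to 88.7 and 86.5, and at a −log10 q of at least 10 to 44.3 and 49.2; with unmatched random lists the chemokine list came to 94.9.

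Angiogenesis factors and receptors had a HOXD13-HA region in 19 of 25 cases against 15.8 (90.9th percentile). The strongest were near ANGPT2 (9.16), a ligand of the endothelial receptor TEK, the VEGF co-receptor NRP1 (8.17), the hypoxia factor HIF1A (7.98) and TIE1 (7.84). Those of ANGPT2, NRP1 and HIF1A lay 13108, 31494 and 42473 bp outside the gene, and that of TIE1 lay inside it. Limb development genes came to 21 of 31 (91.9th), with BMP7 (13.0), PRRX1 (9.35), BMP2 (8.72) and RUNX2 (8.49). Undifferentiated and invasive genes came to 19 of 24 (92.9th), with the ligand WNT5A (16.1), TGFBI (13.8), EGFR (9.37) and TNC (6.95). Melanocytic genes came to 14 of 20 (72.2nd), among them the lineage factors SOX10 (7.14), MITF (6.48) and TFAP2A (5.36), and RAB27A (5.37). MAPK feedback genes came to 13 of 17 (84.6th), with SPRY1 (11.0), EPHA2 (10.8), ETV4 (9.94) and IER3 (7.88). Class 3 semaphorins and plexins came to 7 of 12 (32.3rd), with SEMA3A (7.32), SEMA3C (6.30), SEMA3D (6.12) and PLXNA2 (4.40).

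Antigen presentation genes had a HOXD13-HA region in 5 of 19 cases against 9.93 (1.05th percentile), a low count that rests on the MHC, where the HOXD13-HA list itself is sparse. Without MHC genes, a setting chosen after the results were seen, the 8 genes left came to the 21.7th percentile. The 19 genes form 14 loci, so neighbouring absences are not separate observations. Among them were ERAP1 (11.7), TAPBP (5.75) and NLRC5 (4.57). The 14 without one included B2M and the peptide transporter genes TAP1 and TAP2, named after their values were seen. At a −log10 q of at least 10 the list came to the 56.1st percentile. Housekeeping genes came to 6 of 15 (3.38th), with YWHAZ (5.72), TUBB (5.27) and HPRT1 (3.57). Immune checkpoints and suppressive cytokines came to 9 of 15 (51.1st), with TGFB2 (8.16), CD276 (6.43), SIGLEC15 (5.01) and VTCN1 (4.88). Cohesin and CTCF partners came to 9 of 13 (72.6th), with CTCF itself (11.3), SMC3 (8.66), STAG1 (7.84) and ZNF143 (7.78).

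Lists of other cell types lay between the 54.3rd and the 86.9th percentile. Fibroblast genes came to 9 of 12 (86.9th percentile), with DCN and LUM sharing a region of fold 6.53, ACTA2 (6.08) and PDGFRA (5.38). Endothelial genes came to 9 of 12 (84.3rd), with CLDN5 (10.6), TIE1 (7.84), KDR (7.16) and TEK (6.02). T cell genes came to 9 of 12 (81.5th), with CD3E (12.6), PTPRC (12.3), CD2 (6.05) and CD4 (4.84). Keratinocyte genes came to 8 of 12 (72.6th), with KRT14 and KRT16 sharing a region of fold 13.5, SFN (6.75) and KRT1 (6.33). Hepatocyte genes came to 7 of 12 (54.3rd), with TTR (6.74), FGA (6.16), CYP3A4 (4.58) and ALB (4.31). Of all 19974 protein-coding genes, 58.9% had a HOXD13-HA region within 50 kb, so a region near a single gene is common. Some lists lay above the 95th percentile only under another setting: limb development genes (98.3), endothelial genes (98.9) and cohesin partners (96.4) at a −log10 q of at least 10, limb (97.7) and fibroblast genes (96.1) with 10 kb, endothelial genes (97.6) with 100 kb, and angiogenesis (95.9) and undifferentiated genes (97.9) with unmatched random lists.

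**Figure D3:**
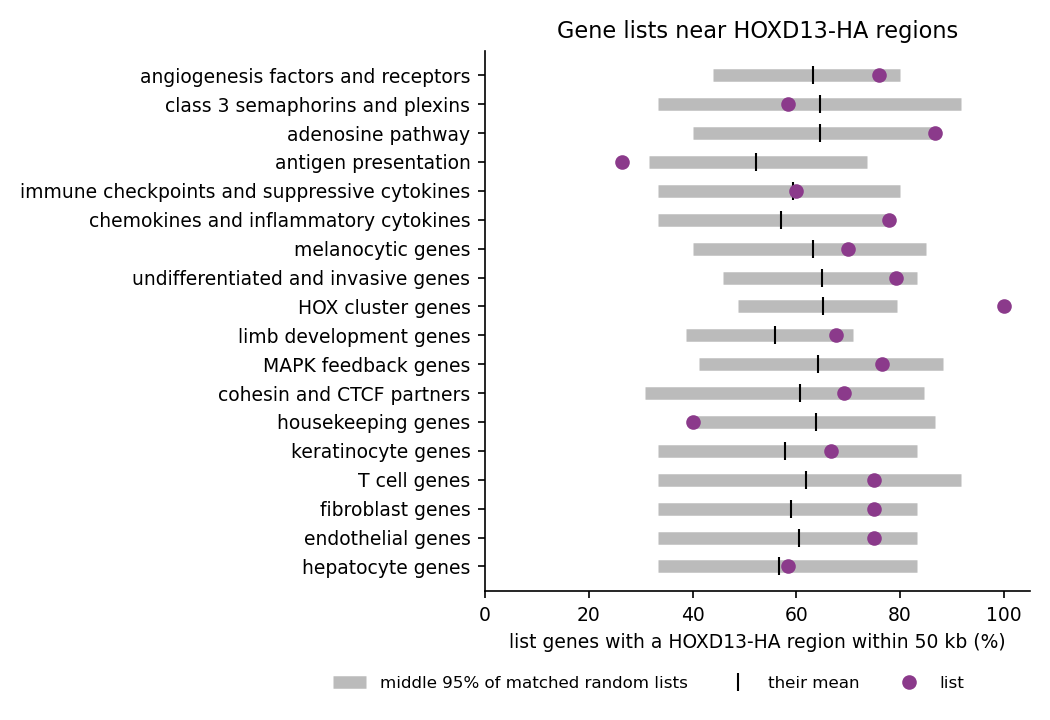
Share of the genes of each of the 18 lists (%) with a HOXD13-HA region within 50 kb of either end (points), beside the mean (ticks) and the middle 95% (bars) of 10000 matched random lists. HOX genes (39 of 39) lay above the random lists, and antigen presentation genes (5 of 19) below.

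Both hairpin libraries of A375 listed far fewer K27ac regions than the shNTC replicates, the comparison that addresses HOXD13 silencing. Of 65337 regions found in both shNTC replicates, 24220 (37.1%, 36.7 to 37.4) were listed in neither shH2 nor shH3. Only 577 of 31235 regions (1.85%) found in both hairpin libraries were in neither shNTC replicate. The other ways of pairing the 4 libraries gave 203 to 1045 regions, or 0.632 to 2.69%. These pairings put an shNTC and a hairpin list on either side, and 88.4 to 94.4% of the hairpin regions lay in each shNTC list. Low counts follow from this nesting and are no background for the lost count. With all lists held to 43634 regions, 6155 of 37488 were lost (16.4%) and 1892 of 29267 gained (6.46%), against 449 to 809 for the other pairings. With 500-bp windows at the summits as well, a setting chosen after the results were seen, 7255 were lost and 5269 gained, against 1041 to 1256 for the other pairings. The lost count without shNTC replicate 1 was 36473 and without replicate 2 it was 41617, and the gained count without replicate 1 was 947. At a −log10 q of at least 10, 8422 were lost and 240 gained; against shH2 alone 1915 were gained, and against shH3 alone 4253.

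The lost regions were mostly weak and lay within genes. In the weakest of 10 strength classes of shNTC regions 81.8% were lost, in the strongest 0.306%. Of the lost regions 59.5% lay in a gene and 13.2% near a gene end, against 40.9% and 25.1% of those kept in at least 1 hairpin library. A375-GFP ATAC overlapped 42.5% of the lost, 91.7% of the kept and 86.0% of the gained regions. The strongest lost region lay 634 bp inside TMEM156 (chromosome 4, 38966240 to 38968515). The next were nearest to SAMD12, IYD, SLC10A2, PLA2G4E, LOC102723475, SLC13A3, SNRPB2, BEST1, a chloride channel gene, and LIPF, and of these 10 regions only that at SLC13A3 overlapped HOXD13-HA. The strongest gained regions were nearest to APCS, FRMD4A, CCND1, the cyclin D1 gene, LINC02798, ZNF608 (2 regions), SYT6, LOC124904228, NTRK2 and GLIS3. None of these 10 overlapped HOXD13-HA. Many of the nearest genes were far from their region. Of the gained regions, that assigned to LINC02798 lay 2670147 bp away and those of ZNF608 385629 and 386514 bp. Those of NTRK2, LOC124904228 and CCND1 lay 197313, 165256 and 144359 bp away. Of the lost regions, those assigned to SLC10A2 and LOC102723475 lay 574636 and 558538 bp away. No filter for repetitive sequence was applied to the lists here.

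K27ac regions that overlap HOXD13-HA were lost less often than other regions of like strength and width. Of 7221 bound shNTC regions 1401 (19.4%) were lost, against 25.1% (23.8 to 26.1) of matched unbound regions, a difference of −5.65 points (−6.43 to −4.93). For shH2 alone the difference was −5.94 points, and for shH3 alone −4.05. It was −2.64 points with lists of equal length, −2.63 at a −log10 q of at least 10 and −3.26 with a match on A375-GFP ATAC overlap, and −19.9 without matching. With equal length and the ATAC match together it was −1.89 points (−2.61 to −1.20), and for shH3 alone −0.481 (−1.37 to 0.413), where no difference was detectable.

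**Figure D4:**
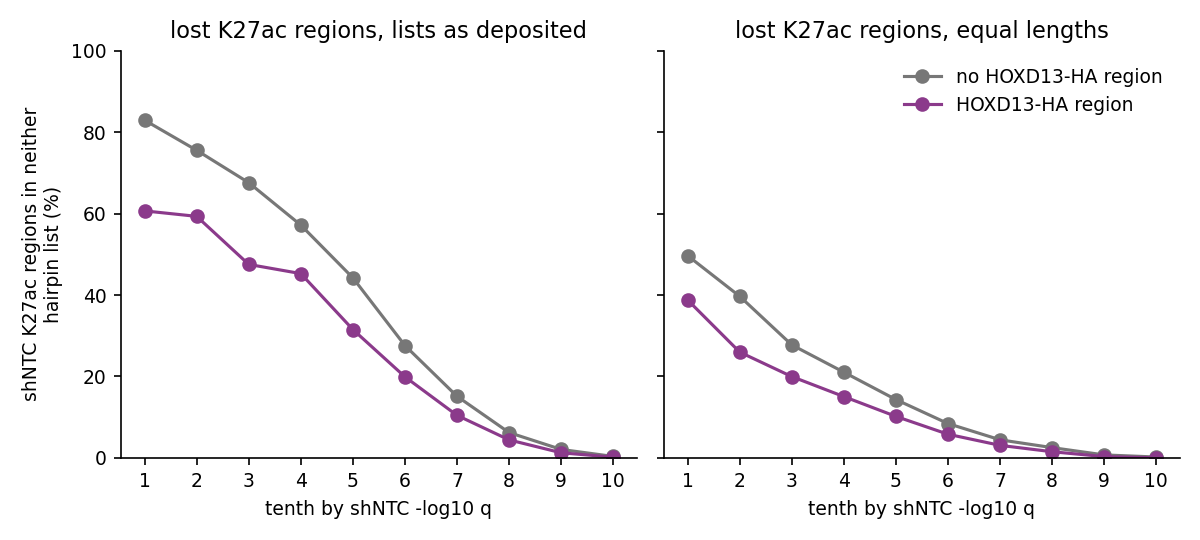
Share of shNTC K27ac regions (%) listed in neither hairpin library, in 10 classes of −log10 q from weakest to strongest, for regions with and without HOXD13-HA, with lists as deposited (left) and of equal length (right). Loss fell with strength in both panels, from 81.8% to 0.306% over all regions as deposited, and was lower with HOXD13-HA in each class.

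Near the lost regions, HOX genes and T cell genes lay above the 95th percentile of matched random lists. Among HOX genes 39 of 39 had a lost region within 50 kb against 36.2 (98.0th percentile), and among T cell genes 12 of 12 against 9.61 (97.2nd). The HOX genes form 4 loci and share regions, so they are not 39 separate observations. The T cell genes form 10 loci, since CD3D, CD3E and CD3G, named after their values were seen, are neighbours. Melanocytic genes lay low, with 12 of 20 against 15.3 (2.32nd), as did housekeeping genes with 10 of 15 (1.69th). The other 14 lists lay between the 12.9th and the 91.7th percentile, with 20 of 25 angiogenesis genes, 11 of 15 adenosine genes, 7 of 19 antigen presentation genes and 13 of 18 chemokine genes. With lists of equal length the HOX list turned to the low side, 17 of 39 against 25.1 (0.21st), T cell genes came to the 92.7th percentile, melanocytic genes to the 48.7th and housekeeping genes to the 72.6th, and hepatocyte genes alone lay above the 95th, with 5 of 12 against 2.35 (97.4th), TTR, FGA, APOA1, AHSG and HP, named after their values were seen. The 17 HOX genes all lay in HOXC and HOXD, and the random lists do not share regions in this way, so neither HOX percentile can be taken at face value. No list lay above the 95th percentile when regions were assigned to the nearest gene end, with 100 kb, for shH2 alone, with regions joined or without shNTC replicate 1, and for shH3 alone the HOX list did (95.7th). At a −log10 q of at least 10 the HOX list came to the 96.0th percentile, undifferentiated genes to the 96.7th, T cell genes to the 93.0th and melanocytic genes to the 86.0th. With 10 kb keratinocyte genes (99.8th) lay above the 95th beside HOX and T cell genes (both 99.6th), and with unmatched random lists cohesin partners (99.6th), MAPK feedback (95.8th) and endothelial genes (95.7th) did too. Without replicate 2 the 1 list above it was the keratinocyte list (95.5th).

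Near the gained regions, keratinocyte genes alone lay above the 95th percentile, with KRT14, KRT16 and DSG3 (3 of 12 against 0.198, 99.95th). KRT14 and KRT16 are neighbours, so they are not separate observations, and DSG3 was named after its values were seen. The other 17 lists had 0 or 1 gene with a gained region, and the single genes, named after their values were seen, were APLN, ADA, TGFB2, WNT5A, GREM1 and COL5A1. Assigned to the nearest gene end, the keratinocyte list came to the 93.2nd percentile, and at a −log10 q of at least 10 to the 47.8th. Angiogenesis genes (98.2nd) and fibroblast genes (95.8th) lay above the 95th at that −log10 q, limb development genes with 100 kb (95.6th), fibroblast genes by nearest gene end (95.4th), and immune checkpoints for shH3 alone (99.2nd). With lists of equal length, limb development genes (6 of 31, 99.6th), semaphorins and plexins (SEMA3B, SEMA3C, SEMA3F and PLXND1, 4 of 12, 98.1st), keratinocyte genes (3 of 12, 98.1st), undifferentiated genes (6 of 24, 95.7th) and adenosine genes (ADA, ADORA2B, DPP4 and ENTPD3, 4 of 15, 95.4th) lay above it. The genes of both lists were named after their values were seen. Without shNTC replicate 2, 3 lists lay above it, with fibroblast genes (96.7th) and undifferentiated genes (99.7th) beside the keratinocyte list.

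VEGFA, SEMA3A and NT5E differed in what lay near them. These genes were chosen in advance from what was known of the study, whose series title names angiogenesis and immune evasion. VEGFA, the main endothelial growth factor, had 1 weak HOXD13-HA region within 50 kb (fold 2.41), outside A375-GFP open chromatin. It had 5 and 7 K27ac regions in the shNTC replicates over 6222 and 6559 bp, and 2 in each hairpin library over 1124 (shH2) and 1691 bp (shH3). Of its 5 regions found in both replicates 4 were lost. SEMA3A, a repellent guidance ligand, had 5 HOXD13-HA regions, none of them in A375-GFP open chromatin. The strongest lay at 84484459 to 84485092 of chromosome 7. At a −log10 q of at least 10 SEMA3A kept 1 HOXD13-HA region, and VEGFA and NT5E kept none. Of the 3 shNTC K27ac regions at SEMA3A 1 was lost. NT5E, which encodes the adenosine-producing enzyme CD73, had 2 HOXD13-HA regions (best fold 3.76), and 2 of its 6 shNTC K27ac regions were lost. With lists of equal length none was lost, of 1 shNTC region at VEGFA, 1 at SEMA3A and 4 at NT5E. By K27ac length within 50 kb, NT5E lay at the 99.4th percentile of genes in SKMEL-147, the 85.3rd in A375-GFP, the 34.4th in 501mel and the 22.3rd in SKMEL-5. K27ac near NT5E covered 23793 and 23119 bp in the shNTC replicates (88.7th and 89.3rd percentile), 11966 bp in shH2 (95.5th) and 14467 bp in shH3 (94.8th), so its length fell while its rank within the shorter lists rose.

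The 4 lines shared few acetylated regions and more open ones. Of 192984 merged K27ac regions 74.9% were in 1 line and 2.89% (5585) in all 4, and of 228532 merged ATAC regions 51.9% were in 1 line and 14.7% (33529) in all 4. By shared K27ac length, 501mel and SKMEL-5 were most alike, with a Jaccard index of 24.4%, and 501mel and SKMEL-147 least, with 8.51%. SKMEL-147 and A375-GFP had 17.0% in K27ac and the highest index in ATAC, 41.7%. SKMEL-5 and A375-GFP had 17.1% in K27ac, and with lists of equal length these pairs had 18.5% and 19.6%. The shNTC replicates had 73.6%, while A375-GFP and shNTC replicate 1, of the same line, had 39.3%, so K27ac lists of A375 also differ between parts of the study. The shNTC and hairpin lists hold regions on alternative copies of sequences and the A375-GFP list does not. Antigen presentation genes, many of them in the MHC, had a median K27ac percentile of 56.6 in A375-GFP and of 5.78 and 5.91 in the shNTC replicates. At a −log10 q of at least 10 the ATAC share in all 4 lines was 9.08%.

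Melanocytic genes were acetylated more widely in 501mel and SKMEL-5 than in SKMEL-147 and A375-GFP, and undifferentiated and invasive genes more widely in SKMEL-147 and A375-GFP than in 501mel. Melanocytic genes had K27ac near a gene end in 15 of 20 cases in 501mel and 18 of 20 in SKMEL-5, against 28.8% and 48.9% of all genes. In SKMEL-147 they had it in 6 of 20 cases and in A375-GFP in 10 of 20, against 27.2% and 58.6% of all genes. The shNTC replicates of A375 had it in 13 and 14 of 20, against 62.1% and 60.8% of all genes, close to the 15 of 501mel. Undifferentiated and invasive genes went the other way, with 4 of 24 in 501mel, 13 of 24 in SKMEL-5, 17 of 24 in SKMEL-147 and 18 of 24 in A375-GFP. At a −log10 q of at least 10 the SKMEL-147 counts were 2 melanocytic and 9 undifferentiated genes. The pigment gene TYRP1 had the widest spread, at the 98.3rd percentile of K27ac length in 501mel, 99.8th in SKMEL-5, 67.0th in SKMEL-147 and 22.1st in A375-GFP. RAB38, OCA2, MLANA, TYR, which encodes tyrosinase, and GPR143 followed. Among undifferentiated genes LOXL2, a collagen cross-linking enzyme, had the widest spread, from the 17.0th percentile in 501mel and 9.84th in SKMEL-5, both without a region near it, to 97.6th in SKMEL-147 and 82.8th in A375-GFP. TNC, AMOTL2, JUN and EGFR followed with their lowest value in 501mel, while SNAI2 was lowest in A375-GFP (26.1st) and at 84.8 and 98.4 in 501mel and SKMEL-5. SOX10, chosen after its values were seen, lay above the 98th percentile in all 4 lines, with a spread of 0.976 points.

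**Figure D5:**
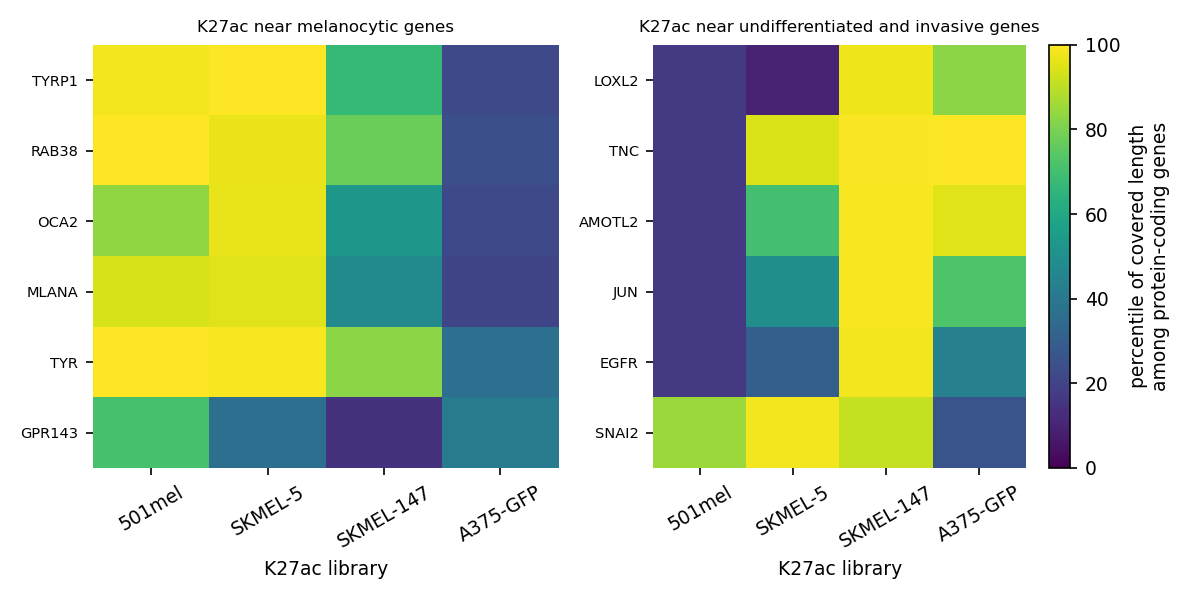
Heat map of the percentile of K27ac length within 50 kb among all protein-coding genes of the same library (colour, 0 to 100), for the 6 melanocytic (left) and 6 undifferentiated genes (right) with the widest spread between lines, in the 501mel, SKMEL-5, SKMEL-147 and A375-GFP libraries. TYRP1 ran from 99.8 in SKMEL-5 to 22.1 in A375-GFP, and LOXL2 from 9.84 in SKMEL-5 to 97.6 in SKMEL-147.

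CTCF sites were largely common to both profiled lines. Of 501mel CTCF regions 76.9% (76.5 to 77.3) were found in SKMEL-5, and 58.3% (57.9 to 58.7) of the longer SKMEL-5 list in 501mel. In the strongest of 10 classes these shares were 99.3% and 96.8%. Open chromatin of the same line covered 84.6% of CTCF regions in 501mel and 52.0% in SKMEL-5, and K27ac covered 16.6% and 28.7%.

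HOXD13-HA was rarely at these CTCF sites, which were mapped in other lines than HOXD13-HA. The HOXD13-HA list had 4.85% (4.61 to 5.11) of its regions in 501mel CTCF regions and 5.22% (4.97 to 5.48) in SKMEL-5 CTCF regions, against random means of 1.20% and 1.72%. For CTCF regions found in both lines the shares were 3.29% and 3.45%. Bound A375-GFP ATAC regions were CTCF sites of 501mel in 15.0% of cases against 27.4% of unbound ones of the same strength, a difference of −12.3 points (−13.2 to −11.5). With SKMEL-5 CTCF the shares were 15.8% and 31.8%, a difference of −16.0 points (−16.9 to −15.1). Bound regions were also less often open in those lines than unbound ones of like strength and width, by −13.7 points in 501mel and −8.67 in SKMEL-5. With a match on strength, width and ATAC overlap in the same line, chosen after the results were seen, the CTCF differences were −5.54 points (−6.24 to −4.91) and −11.3 (−12.1 to −10.5).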

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

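The counts below describe summits outside the region lists, and no explanation of them was tested. The HOXD13-HA summit list held 13 summits with no region in the region list, 8 of them on chromosome 21, which no comparison used. The SKMEL-5 ATAC summit list held 5 such summits, the SKMEL-147 ATAC list 7 and the 501mel ATAC list 2, all on the mitochondrial genome.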

How the results depend on the processing

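The gene body window, the match on ATAC overlap and the lists without MHC genes were chosen only after the results were seen. Loss at HOXD13-HA stayed negative under every alternative, and the other values are counts or shares, which have no sign. Near lost regions the HOX list went from the 98.0th to the 0.21st percentile with equal list lengths, and melanocytic genes from the 2.32nd to the 86.0th at a −log10 q of at least 10. The HOX genes form 4 loci, so neither HOX percentile rests on separate genes. Of the values for comparisons 33 stayed within counting error or 1.5 times, and 53 moved; of the values for single lists, genes and libraries 119 stayed and 88 moved. The cause was not tested except where noted. At a −log10 q of at least 10, HOXD13-HA shares were 41.0% in ATAC, 13.7% in K27ac, 4.84% near a gene end and 3.57 and 4.00% at 501mel and SKMEL-5 CTCF; lost and gained regions were 8422 and 240, loss at HOXD13-HA −2.63 points, and lists near gained regions 2. CTCF sharing was then 82.3%, and 2.42% of K27ac and 9.08% of ATAC regions were in all 4 lines. With an overlap of at least 50% of the shorter region, shares were 31.5% (ATAC), 17.8% (K27ac), 4.06 and 4.32% (CTCF), and CTCF sharing 75.4%; by summits alone they were 31.4% (ATAC) and 16.3% (K27ac). With equal list lengths, the K27ac share was 20.1%, lost and gained 6155 and 1892, loss at HOXD13-HA −2.64 points, lists near lost and gained regions 1 and 5, CTCF sharing 69.2%, and shares in all 4 lines 3.80% (K27ac) and 18.5% (ATAC). Near a gene end lay 3.02% within 1 kb and 10.5% within 5 kb, as a shorter or longer distance must give. Lists near lost regions numbered 0 with 100 kb, 0 by nearest gene end, 0 for joined regions, 0 for shH2 alone, 1 for shH3 alone and 5 unmatched; lists near gained regions 2 with 100 kb and 2 for shH3 alone; lists near HOXD13-HA 1 by nearest gene end. Gained regions were 1915 against shH2 alone and 4253 against shH3 alone, which ask for 1 list instead of both. Loss at HOXD13-HA was −4.05 points for shH3 alone, −19.9 unmatched and −3.26 matched on ATAC overlap. At CTCF regions of both lines the shares were 3.29 and 3.45%. Without either shNTC replicate, lost regions were 36473 to 41617, gained 787 to 947, loss −6.97 to −6.07 points, lists near lost regions 0 to 1 and near gained regions 1 to 3. Motif counts and their alternatives were not run, and neither was the CTCF-motif filter, since they need the genome sequence. No coordinates were shared by regions of a list, so counting every summit changes nothing, and the overlap rule cannot act on merged regions of the lines. Depth is unknown, so a region missing from a shorter list was not shown to lack signal.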

Other observations

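The lists in this paragraph and the comparison of bound open regions with other lines were chosen after the results were seen, as were the explanations tested below. Only for those on finer strength classes (−5.57), gene ends (12.0), A375 acetylation (11.8 and 9.42) and openness in the same line (3.94) was the prediction written before the test was run. The loss at HOXD13-HA, the lost and gained counts and their values with equal list lengths were planned. Beyond the pigment and invasive genes, acetylation near gene ends of the MAPK feedback list, negative regulators and targets of ERK signalling, was frequent in every line, with 13 of 17 genes in 501mel, 16 in SKMEL-5, 13 in SKMEL-147 and 17 in A375-GFP, against 28.8%, 48.9%, 27.2% and 58.6% of all genes. Housekeeping genes had it about as often, in 11, 14, 10 and 14 of 15 cases, and cohesin partners in 6, 13, 11 and 13 of 13, so the frequency is one that housekeeping genes share. Angiogenesis genes lay highest in SKMEL-147, with a median K27ac percentile of 84.5 against 62.1 in A375-GFP, 53.1 in SKMEL-5 and 47.6 in 501mel. Some lists of other cell types were highest there too, with fibroblast genes at 72.9 against 33.0 in A375-GFP and keratinocyte genes at 50.7 against 27.3. By gene ends angiogenesis genes were acetylated in 52% (13 of 25) in SKMEL-147 against 27.2% of all genes, and in 60% (15 of 25) in A375-GFP against 58.6%. The shares were 40% in SKMEL-5 against 48.9%, and 32% in 501mel against 28.8%.

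HOXD13-HA-bound open regions of A375 were more often acetylated in SKMEL-147, where HOXD13-HA was not profiled. Of 9747 bound A375-GFP ATAC regions 34.7% overlapped SKMEL-147 K27ac, against 20.7% of unbound regions of like strength and width, a difference of 13.9 points (13.2 to 14.7). Among regions away from gene ends it was 12.0 points (11.2 to 12.8), and with a match on A375-GFP K27ac 11.8 points (11.0 to 12.6). Bound regions were also more often acetylated in A375 itself, by 8.98 points in A375-GFP and 14.6 and 14.4 in the shNTC replicates. With a match on all 3 lists 9.42 points (8.69 to 10.2) were left, so neither gene ends nor overlap with a listed A375 K27ac region accounts for the whole of it. The match used overlap alone, not the strength or width of K27ac, so stronger A375 acetylation at bound regions was not excluded. In 501mel and SKMEL-5 the differences were at most 2.02 points, but bound regions were less often open there, by −13.7 and −8.67 points, and not in SKMEL-147 (1.12). With a match on ATAC overlap in the same line the differences were 3.94 (3.37 to 4.56), 2.79 and 13.7. Being listed as open thus does not account for the whole of the contrast between lines. The strength of the ATAC signal in those lines was not matched, and the cause stays open.

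More K27ac regions were lost than gained with the hairpins, 42.0 times as many as deposited. With equal list lengths the ratio was 3.25, so list length is not the whole of it. With equal lengths and 500-bp windows at the summits 7255 were lost and 5269 gained, a ratio of 1.38, which is consistent with the wider shNTC regions adding to the rest; the other pairings gave 1041 to 1256. The hairpin libraries also resembled each other less, with 77.6% of shH2 regions found in shH3 against 88.5% between shNTC replicates. Equal lengths assume equal totals and list length goes with the hairpins, so a true overall loss of acetylation stays open.

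K27ac regions bound by HOXD13-HA were lost less often than matched ones, a difference of −5.65 points, and whether acetylation at tagged sites depends on HOXD13 more than elsewhere has no test apart from this value and stays open. The difference was −5.57 points in 50 classes of strength and 20 of width, −3.26 points with a match on A375-GFP ATAC overlap and −2.64 points with equal list lengths, so none of these alone accounts for the whole of it. The ATAC match used overlap alone, not the strength of the ATAC signal. With equal lengths and the ATAC match together it was −1.89 points, and −0.481 (−1.37 to 0.413) for shH3 alone, so together they may account for much of it, and for shH3 no difference was detectable. Sites of overexpressed, tagged HOXD13 may also differ from those of the cell's own HOXD13, which was not tested.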
